A study of Mus musculus with 32 samples.

How the data were processed

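RNA from whole mouse livers was measured on 32 Illumina mouse BeadChip arrays, 1 array per mouse. The labels give C57BL/6 females, infected with Schistosoma japonicum or uninfected, with or without the anthelmintic praziquantel. The mice fall into 11 groups. Untreated infected mice were sampled at weeks 6, 10, 13 and 14, infected mice given praziquantel at weeks 10, 13 and 14, and uninfected mice given praziquantel at weeks 10, 13 and 14, with 3 mice in each of these groups. The remaining group holds 2 uninfected, untreated mice at week 0. The 32 arrays lie on 4 BeadChips with 8 arrays each. For arrays, the number per group limits the precision.

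The deposited non-normalized table gives for each probe and array an intensity, the mean bead signal on a linear scale, neither background subtracted nor scaled between arrays. Per the submitters' processing notes it was made with GenomeStudio 1.1.1. The same deposited table gives beside each intensity a detection score, relative to the negative control beads of the array. Its header calls that column a detection p, but the value rises with the signal (lowest Spearman rho over the arrays 0.965, across probes, which are not independent replicates), so 1 minus the score was used as the detection p. The deposited series matrix holds log2 values: the authors' log2 of the same intensity, minus the 75th percentile of the array, minus the median of the probe over the arrays. Recomputing it in that way gave a largest absolute difference of 0.000584. Both tables hold 25697 probes. The lowest intensity was 85.8 and the highest 56156.2.

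The intensities were corrected for background by normexp, with the background inferred from the detection p, given an offset of 16, quantile normalized and set on the log2 scale, with neqc of limma 3.58.1 in R 4.3.3. Probes were joined to gene symbols by the annotation of the array: 23978 probes had 1 symbol, 1719 had none and 0 had several. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which left 15357. The kept probe with the highest mean over all arrays stood for its gene. This gave 11536 genes tested, 10608 under a symbol and 928 under a probe identifier. Of the genes named, 69 have several kept probes. For 5 of these, probes were called in opposite directions in some of the comparisons checked (the 3 means and week 6, defined below). These were Ddx6 (week 6), Nfic (infection, treatment and week 6), Acta2 (residual), Actb (residual and week 6) and Gusb (infection). Positions are those of GRCm38.p6.

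One linear model with a mean per group was fitted to all 32 arrays with limma (lmFit and eBayes, 21 residual degrees of freedom), so that every comparison shares 1 estimate of the spread per gene. Tests were two-sided, and a gene was called when its p, adjusted by Benjamini-Hochberg over all genes tested, was under 0.05. The infection comparison is untreated infected minus uninfected, the treatment comparison is treated infected minus untreated infected, and the residual comparison is treated infected minus uninfected. Each was made at weeks 10, 13 and 14 and as the mean of the 3 weeks. The comparisons share groups, so infection and treatment use the same infected arrays and mirror each other in part. Week 6 infected was compared with week 0 uninfected, and groups of 1 kind were compared between weeks. The replicate numbers pair no mice, so no pairing was used. Uninfected mice of weeks 10 to 14 had praziquantel and untreated infected mice had none, so the infection comparison at those weeks also contains any effect of the drug itself.

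The genes named in the text follow a rule. For the 3 means and week 6, it takes the 8 genes with the largest estimated change in each direction among those called, with 1 symbol and with no overlap between the arrays compared (within each week for the means). For the comparisons over time and the differences between effects it takes 5 in each direction. For each of 31 gene lists it adds up to 4 members with the largest absolute change. The design, this rule, the gene lists and most alternatives were fixed before the data were examined. Exceptions to the direction of a list, and a few other genes, were named after their values were seen. The lists hold markers of cell types and members of pathways: extracellular matrix, stellate cells, matrix remodelling, eosinophils, type 2 response, macrophages, neutrophils, T cells, B cells, NK cells, interferon-stimulated genes, mast cells, MHC class II, cell cycle, P450 and drug metabolism, bile acids, fatty acid oxidation, cholesterol synthesis, lipogenesis, urea cycle and amino acids, glucose, plasma proteins, acute phase, cholangiocytes, endothelium, oxidative stress, erythroid and iron, circadian clock, pancreas, fat and muscle, and reference genes. Some genes are in several lists. Each list was tested with camera (preset correlation 0.01, Benjamini-Hochberg over the 31 lists of a comparison), with camera and an estimated correlation, and with fry. Errors of log2 changes are SE from the model, and errors of group means are SD.

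A week 6 score was computed for each array of weeks 10, 13 and 14: the mean log2 value of the genes called and at least 2-fold higher (or lower) at week 6 against week 0, minus the mean of the 9 uninfected arrays of weeks 10, 13 and 14. The genes come from other arrays than those scored. Scores were compared by an exact permutation test within weeks. A gene detected on no array of a group has no measured level there, so its fold is given as a bound, "at least N-fold", computed from the detection limit of the arrays. In a mean over weeks, this applies to each week in which the lower group was detected on no array. List medians are also given with such genes at their bound.

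The fit was also tested on simulated data with known changes, with levels and spreads taken from these arrays. The simulated noise was independent between genes and arrays, with no BeadChip effect. Of 100 genes changed 2-fold, 77 were recovered for infection at week 10, 94 for the infection mean and 74 at week 6. False calls numbered 8, 14 and 5. Only 200 of 11536 genes were changed, far fewer than were called in the arrays. The shares recovered therefore do not give the sensitivity of the real comparisons. Alternatives were no background correction, median scaling, the series matrix values, no filter and a stricter one (detection p under 0.01 on at least 6 arrays, 11813 probes), all probes, the BeadChip as a fixed or random block, differences within single BeadChips, a replicate block, only the arrays compared, array weights, an eBayes prior with trend and robust, and leaving out each array in turn. For the week 6 score they were the top 100 genes, the median, the series matrix and BeadChip means removed. The blocked fits used statmod 1.5.0. Figures were drawn with matplotlib 3.10.9.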

Results

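Transcript levels were measured in 32 livers. Untreated infected mice (weeks 6, 10, 13 and 14 after infection), infected mice given praziquantel by mouth after week 7 (weeks 10, 13 and 14) and uninfected mice given praziquantel (weeks 10, 13 and 14) had 3 mice per week, and uninfected, untreated mice at week 0 numbered 2 (the series description gives 3 for each group). The median raw signal of an array lay between 113.7 and 164.1, and 11194 to 13065 probes per array were detected. The number of arrays limits the precision. The first principal component of the tested genes held 66.4% of the variance. Along it uninfected week 10 replicate 1 (19.6, the others of its group 45.7 and 48.4) and treated week 13 replicate 3 (6.31, the others 33 and 34.6) stood apart from their groups. They are called the 2 arrays that stand apart below. Untreated week 10 replicate 2 (−80, the others −52.7 and −48.5) lay as far from its group. It is not one of these 2 and was left out only when single arrays were left out in turn. In the text below, treated means infected and given praziquantel, and levels are on the log2 scale after normalization.

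The infection comparison asks how untreated infected livers differed from uninfected ones at weeks 10, 13 and 14 (9 against 9 arrays, mean over the 3 weeks). The largest rise was in Ltf (lactoferrin, chromosome 9, 111019292 to 111042766), which rose by 8.24 ± 0.51 (SE). Camp (cathelicidin) rose by 7.64 ± 0.48, S100a9 (a calprotectin subunit, chromosome 3, 90692630 to 90695721) by 7.45 ± 0.54 and S100a8 by 6.86 ± 0.55. Mpo (myeloperoxidase, chromosome 11, 87793784 to 87804412) was at least 118-fold, Retnlg at least 92-fold, the eosinophil granule gene Prg2 (chromosome 2, 84980461 to 84983632) at least 83.4-fold and Prtn3 (proteinase 3) at least 80.1-fold higher. In uninfected livers, Ltf and Camp were detected on 4 of 9 arrays and Mpo, Retnlg, Prg2 and Prtn3 on 1 of 9. The P450 gene Cyp2b13 (chromosome 7, 26061388 to 26096197) fell from 12.45 ± 1.37 to 5.41 ± 1.48 (SD, n = 9 each). Among genes with 1 symbol and no overlap between the arrays within each week, the others with the largest falls were A1bg (at least 110-fold), the sulfotransferase Sult2a8 (chromosome 7, 14410686 to 14446780, at least 59.8-fold), Cyp2b23 (−5.86 ± 0.30), the carbonic anhydrase Car3 (−5.72 ± 0.35), the acyl-CoA thioesterase Acot3 (at least 39.6-fold), Cyp4a31 (−4.78 ± 0.43) and Cyp2b9 (−4.62 ± 0.37). Of these 8, A1bg was detected on 1, Sult2a8 on 3, Cyp2b13 on 4, Acot3 on 5, Cyp2b23 and Cyp4a31 on 6 and Car3 on 8 of 9 infected arrays. Adjusted p was at most 3e-10 for these 16 genes.

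In all, 7156 of 11536 genes were called, 3758 higher and 3398 lower, and 2046 of them changed at least 2-fold (1241 higher, 805 lower). With the BeadChip as a fixed block 7283 were called. Within single BeadChips, 108 of the 127 genes named for this comparison had the same sign in each of 8 differences. No list call in any comparison holds with camera's estimated correlation. By camera with the preset correlation 21 of the 31 lists were called here, and by fry 28. Fry tests only whether the genes of a list move one way on balance and does not compare them with other genes.

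All 16 neutrophil genes rose (16 adjusted over the list alone, median 5.72, 5.54 with undetected genes at their bound, adjusted p = 9.04e-10, and adjusted p = 0.177 with an estimated correlation). Of 22 macrophage and Kupffer cell genes, 21 rose (21 adjusted over the list alone, median 2.02, adjusted p = 9.09e-10, and adjusted p = 0.186 with an estimated correlation). The endotoxin coreceptor gene Cd14 (4.21 ± 0.21), Gpnmb (at least 12-fold), Lgals3 (a galectin, 3.59 ± 0.24) and Marco (2.91 ± 0.19) were among them, and Timd4 was at 0.10. The 6 eosinophil genes rose (6 adjusted over the list alone, median 2.34, 1.77 at the bound, adjusted p = 0.000965, and adjusted p = 0.212 with an estimated correlation). Ear10 was at least 6.44-fold, Prg3 at least 3.62-fold and Epx (eosinophil peroxidase) at least 3.2-fold higher. Of 22 type 2 response genes 12 rose and 0 fell (12 adjusted over the list alone, median 0.45, 0.30 at the bound, adjusted p = 0.00447, and adjusted p = 0.212 with an estimated correlation). The chitinase-like Chil3 was at least 69.3-fold and Retnla at least 3.87-fold higher, and Tgm2 changed by 1.80 ± 0.11. Mast cell and basophil genes rose in 5 of 6 (5 adjusted over the list alone, median 1.01, 0.53 at the bound, adjusted p = 0.0138, and adjusted p = 0.225 with an estimated correlation), led by the histidine decarboxylase Hdc (3.55 ± 0.16).

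T cell genes rose in 12 of 18 and fell in 0 (12 adjusted over the list alone, median 0.52, 0.38 at the bound, adjusted p = 0.00482, and adjusted p = 0.268 with an estimated correlation). Cd3d changed by 2.35 ± 0.24 and Cd8b1 by 2.20 ± 0.21. Of 15 NK cell and type 1 response genes 10 rose and 0 fell (10 adjusted over the list alone, median 0.75, 0.36 at the bound, adjusted p = 0.00157, and adjusted p = 0.212 with an estimated correlation), the chemokine gene Ccl4 by 3.48 ± 0.22. MHC class II genes rose in 10 of 13 and fell in 0 (10 adjusted over the list alone, median 1.70, 1.61 at the bound, adjusted p = 0.000581, and adjusted p = 0.259 with an estimated correlation). H2-DMb1 changed by 3.41 ± 0.25 and H2-Aa by 2.74 ± 0.26. Neither the B and plasma cell list (8 higher, 1 lower, the plasma cell surface gene Sdc1, 5 not called, 9 adjusted over the list alone, median 0.68, 0.29 at the bound, adjusted p = 0.119) nor the interferon-stimulated list (11 higher, 5 lower, 9 not called, 16 adjusted over the list alone, median 0.10, adjusted p = 0.477) was called. Mzb1, a plasma cell gene, rose by 4.36 ± 0.40. Gbp2 (1.79 ± 0.21) and Oas1g (1.70 ± 0.17) rose, and Oasl1, Mx1, Usp18, Ifih1 and Ddx58 fell.

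Of 22 extracellular matrix genes 16 rose and 0 fell (17 adjusted over the list alone, median 1.20, 1.05 at the bound, adjusted p = 0.0006, and adjusted p = 0.353 with an estimated correlation). Among them were the crosslinking enzyme gene Loxl1 (2.98 ± 0.38), the collagen gene Col1a2 (chromosome 6, 4505618 to 4541543, 2.42 ± 0.35), Lum (1.98 ± 0.32) and Thbs2 (1.98 ± 0.27). Stellate cell and myofibroblast genes rose in 17 of 21 (18 called adjusted over the list alone, median 1.05, 1.01 at the bound, adjusted p = 0.000176, and adjusted p = 0.212 with an estimated correlation). Timp1 (a metalloproteinase inhibitor) was at least 35.2-fold higher and Acta2 (smooth muscle actin) rose by 2.30 ± 0.24, while Tpm2 fell (−0.80). Remodelling enzymes and inhibitors rose in 19 of 23 (20 called adjusted over the list alone, median 0.91, 0.89 at the bound, adjusted p = 9.06e-05, and adjusted p = 0.212 with an estimated correlation). Mmp9 changed by 4.56 ± 0.25, Mmp12 was at least 5.88-fold higher, and the cathepsin gene Ctsl fell (−0.79). Cholangiocyte and progenitor genes rose in 7 of 15 (8 called adjusted over the list alone, median 0.31, adjusted p = 0.0148, and adjusted p = 0.225 with an estimated correlation). Anxa2 (3.15 ± 0.16) and the growth factor gene Igf2 (2.19 ± 0.29) rose most, and Krt23 fell. Endothelial genes rose in 13 of 25 and fell in 3 (16 called adjusted over the list alone, median 0.38, adjusted p = 0.014, and adjusted p = 0.353 with an estimated correlation). The adhesion genes Vcam1 (2.02 ± 0.15) and Selp (1.83 ± 0.12) and Vwf (von Willebrand factor, chromosome 6, 125552948 to 125686679, 1.88 ± 0.11) rose, and Oit3, Dnase1l3 and Tek fell. Cell cycle genes rose in 20 of 24 (22 called adjusted over the list alone, median 1.92, 1.80 at the bound, adjusted p = 1.78e-06, and adjusted p = 0.212 with an estimated correlation). Prc1 changed by 3.12 ± 0.24 and Cdc20 by 2.97 ± 0.24, and the thymidylate enzymes Tyms (−0.31) and Tk1 (−1.11) fell.

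Of 42 P450 and drug metabolism genes 35 fell (37 called adjusted over the list alone, median −1.37, −1.22 at the bound, adjusted p = 2.09e-10, and adjusted p = 0.177 with an estimated correlation). Cyp2b10 was at least 17.4-fold lower and Cyp2a5 changed by −4.07 ± 0.32, while Cyp2d9 (2.61 ± 0.34) and Gstp1 (0.82) rose. Urea cycle and amino acid genes fell in 30 of 33 and rose in 0 (31 adjusted over the list alone, median −1.06, adjusted p = 5.41e-10, and adjusted p = 0.177 with an estimated correlation), with Cth at −3.23 ± 0.21, Asl (argininosuccinate lyase) at −2.77 ± 0.27 and Otc at −2.25 ± 0.15. Fatty acid oxidation genes and PPARA targets fell in 23 of 27 (24 called adjusted over the list alone, median −1.17, adjusted p = 2.49e-08, and adjusted p = 0.212 with an estimated correlation). Cyp4a14 changed by −4.75 ± 0.71, while Acaa1a rose (0.27). Bile acid genes fell in 18 of 23 (20 called adjusted over the list alone, median −1.13, adjusted p = 5.1e-07, and adjusted p = 0.177 with an estimated correlation). Among these were the export pump gene Abcb11 (−2.63 ± 0.13), Cyp8b1 (−2.50 ± 0.35) and the uptake carrier gene Slc10a1 (−2.20 ± 0.19), while Acox2 rose (0.37). Glucose genes fell in 13 of 20 (15 called adjusted over the list alone, median −0.57, adjusted p = 0.00157, and adjusted p = 0.212 with an estimated correlation). The transporter Slc2a2 changed by −2.25 ± 0.21, and Igfbp1 (1.28) and Tkfc (0.48) rose. Lipogenesis and lipid storage genes fell in 13 of 25 and rose in 5 (Scd2, Dgat1, Cidea, Plin4 and Lpl, 18 called adjusted over the list alone, median −0.53, adjusted p = 0.023, and adjusted p = 0.353 with an estimated correlation). Me1 changed by −2.26 ± 0.26 and Lpl (lipoprotein lipase) by 3.52 ± 0.27.

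Acute phase genes rose in 24 of 29 (26 called adjusted over the list alone, median 1.01, adjusted p = 5.1e-07, and adjusted p = 0.212 with an estimated correlation). Lcn2 (lipocalin 2, chromosome 2, 32384637 to 32387739) rose by 6.65 ± 0.43, Saa1 (serum amyloid A, chromosome 7, 46740497 to 46743181) by 5.87 ± 0.49 and Saa3 by 4.92 ± 0.21, and the hepcidin genes Hamp (−0.38) and Hamp2 (−3.25 ± 0.24) fell. Several of these groups also differed within the uninfected week 10 group, where replicate 1 lay above the other 2 arrays by a median of 2.60 in the neutrophil, 0.96 in the cell cycle, 0.92 in the erythroid, 0.76 in the acute phase and 0.65 in the macrophage list, and at −0.78 in fatty acid oxidation, −0.40 in P450 and −0.40 in matrix genes. The infected week 10 arrays lay from the same 2 arrays by 6.14, 2.21, 0.86, 0.86, 2.62, −1.60, −1.37 and 1.32. Without that array and treated week 13 replicate 3, 7116 genes were called.

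The remaining lists were not called by camera. Plasma protein genes rose in 18 and fell in 20 of 52 (38 adjusted over the list alone, median −0.02, adjusted p = 0.463), with Serpina6 at −3.08 ± 0.21 and the complement gene C6 at 2.89 ± 0.18. Cholesterol synthesis genes fell in 6 and rose in 2 of 18 (Insig1 and Srebf2, 8 adjusted over the list alone, median −0.19, adjusted p = 0.121). Oxidative stress genes rose in 10 and fell in 9 of 28 (19 adjusted over the list alone, adjusted p = 0.865). Their median was −0.12 (−0.03 at the bound) and their mean 0.18, and camera gave a downward and fry an upward direction. The phagocyte oxidase gene Ncf4 rose by 3.71 ± 0.18 and Gsta2 fell (−2.79 ± 0.21). Erythroid and iron genes rose in 8 and fell in 4 of 14 (Klf1, Fech, Hebp1 and Fth1, 12 adjusted over the list alone, median 0.63, 0.57 at the bound, adjusted p = 0.463), led by Slc4a1 (at least 8.11-fold). Clock genes rose in 4 (Per1, Bhlhe40, Nfil3 and Nampt) and fell in 7 of 18 (11 adjusted over the list alone, median −0.37, −0.34 at the bound, adjusted p = 0.121), with Dbp at −3.27 ± 0.36. In the lists for tissue carried over at dissection, 1 of 11 pancreas genes rose (the trypsin inhibitor gene Spink1, at least 43-fold) and 1 fell (Cela1, −0.76 ± 0.24, 0.036 within BeadChip 4, 2 adjusted over the list alone, median 0.47, 0.15 at the bound, adjusted p = 0.423). Of the 8 fat and muscle genes 4 (Car3, Adipor2, Mylpf and Actn3) fell (4 adjusted over the list alone, median −0.20, 0 at the bound, adjusted p = 0.0918). Reference genes rose in 6 and fell in 1 of 12 (Tbp, 8 adjusted over the list alone, median 0.29, adjusted p = 0.121), with Actb at 1.37 ± 0.08 and Ywhaz at 1.24 ± 0.12.

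**Figure D1:**
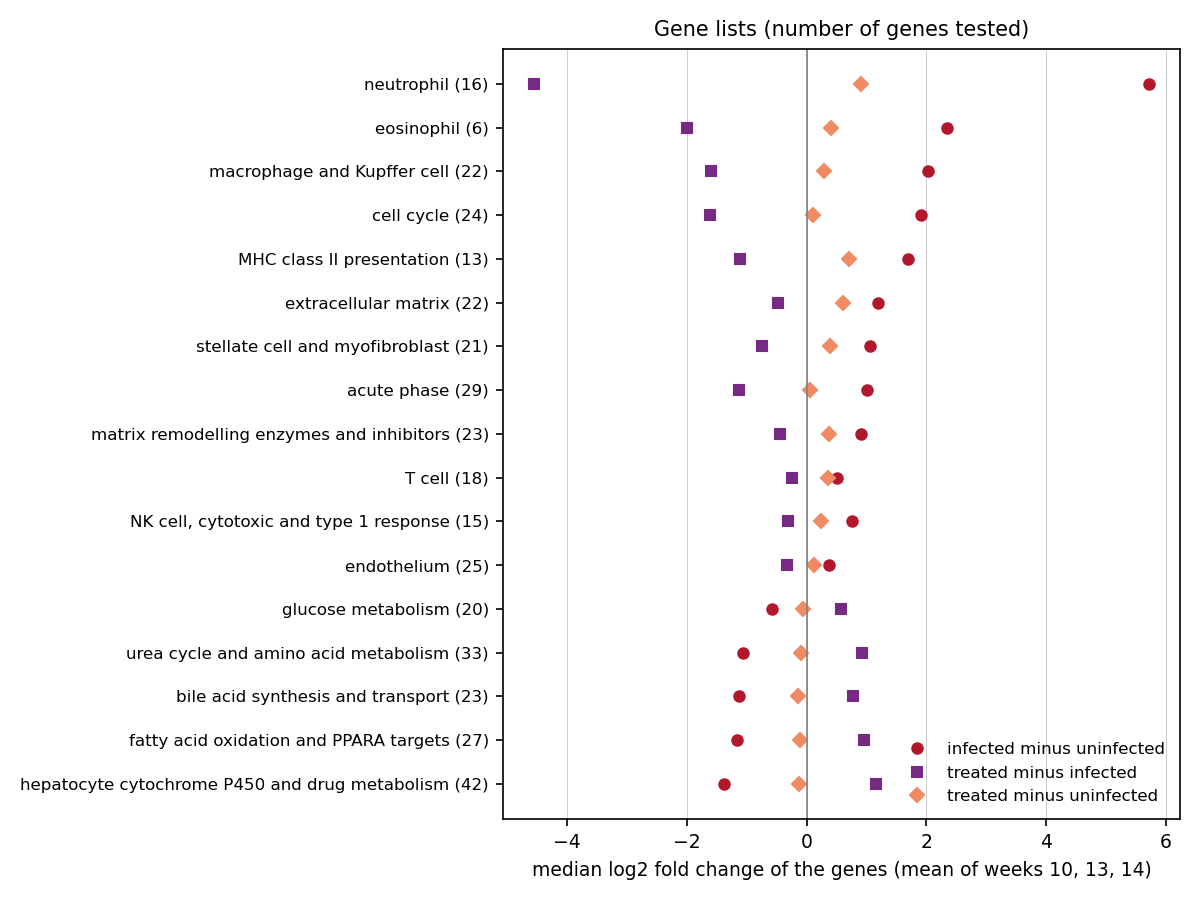
Median log2 change of gene lists in the mean infection, treatment and residual comparisons, 1 point per list and comparison. The neutrophil list lies at 5.72 for infection, −4.55 for treatment and 0.91 for the residual comparison.

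The treatment comparison asks what praziquantel changed in infected livers (9 treated against 9 untreated arrays). It shares the untreated infected arrays with the infection comparison, so mirrored directions are in part built in. Cyp2b13 rose by 6.46 ± 0.48 (88.1-fold), Sult2a8 by at least 46.9-fold, Cyp4a14 by 4.99 ± 0.71, Cyp2b23 by 4.94 ± 0.30, Acot3 by at least 28.3-fold, Car3 by 4.87 ± 0.35, Cyp2b9 by 4.57 ± 0.37 and Cyp4a31 by 4.33 ± 0.43. Lower in treated livers were Prtn3 (−5.95 ± 0.59), Mpo (−5.84 ± 0.35), Ltf (−5.81 ± 0.51), Saa1 (−5.50 ± 0.49), Camp (−5.35 ± 0.48), Lcn2 (−5.32 ± 0.43), the neutrophil protease gene Ctsg (at least 31.7-fold) and Ngp (at least 33-fold). Of the genes detected on only some arrays, Sult2a8 was detected on 3, Cyp2b13 on 4, Acot3 on 5, Cyp2b23 and Cyp4a31 on 6 and Car3 and Cyp4a14 on 8 of 9 untreated arrays, and Prtn3 on 5, Mpo on 6, Ctsg on 4 and Ngp on 5 of 9 treated arrays. In all 5761 genes were called (2892 higher, 2869 lower), 1168 of them at least 2-fold (417 higher, 751 lower), and 5911 with the BeadChip as a block. Within BeadChips 99 of 121 named genes had the same sign in each of 8 differences. Without the 2 arrays that stand apart, 5836 genes were called. Untreated week 10 replicate 2, as far from its group on the first principal component, was kept in that count. Leaving out this array alone gave 5423, the lowest count with any single array left out. Camera called 19 lists and fry 26.

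All 16 neutrophil genes fell (16 adjusted over the list alone, median −4.55, adjusted p = 1.16e-12, and adjusted p = 0.0853 with an estimated correlation). Macrophage genes fell in 21 of 22 (21 adjusted over the list alone, median −1.60, adjusted p = 3.97e-12, and adjusted p = 0.101 with an estimated correlation). Cd14 changed by −3.79 ± 0.21 and Marco by −2.87 ± 0.19. The member not called was Gpnmb (0.27 ± 0.36, adjusted p = 0.582). Eosinophil genes fell in 5 of 6 (5 adjusted over the list alone, median −2.0, −1.83 at the bound, adjusted p = 0.000602, and adjusted p = 0.142 with an estimated correlation). Prg2 changed by −4.34 ± 0.44. Type 2 response genes fell in 13 of 22 (14 called adjusted over the list alone, median −0.42, −0.39 at the bound, adjusted p = 0.00305, and adjusted p = 0.153 with an estimated correlation), Chil3 by the most (−4.71 ± 0.39), and Arg1 (arginase) rose (0.26). Mast cell genes fell in 5 of 6 (5 adjusted over the list alone, median −0.83, −0.64 at the bound, adjusted p = 0.00592, and adjusted p = 0.196 with an estimated correlation). MHC class II genes fell in 8 of 13 (8 adjusted over the list alone, median −1.12, adjusted p = 0.00209, and adjusted p = 0.333 with an estimated correlation). NK cell and type 1 genes fell in 6 of 15 (6 adjusted over the list alone, median −0.32, −0.19 at the bound, adjusted p = 0.0128, and adjusted p = 0.323 with an estimated correlation). Acute phase genes fell in 24 of 29 (26 called adjusted over the list alone, median −1.12, adjusted p = 7.15e-10, and adjusted p = 0.107 with an estimated correlation), while Hamp (0.35) and Hamp2 (3.26 ± 0.24) rose. Cell cycle genes fell in 20 of 24 (21 called adjusted over the list alone, median −1.62, adjusted p = 9.68e-10, and adjusted p = 0.131 with an estimated correlation). Prc1 changed by −2.49 ± 0.24, and Tk1 rose (0.82).

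P450 and drug metabolism genes rose in 36 of 42 (38 called adjusted over the list alone, median 1.16, 1.06 at the bound, adjusted p = 6.61e-13, and adjusted p = 0.0853 with an estimated correlation). Cyp2a5 changed by 3.85 ± 0.32, while Cyp2d9 (−1.80) and Gstp1 (−0.98) fell. Urea cycle and amino acid genes rose in 32 of 33 (33 adjusted over the list alone, median 0.93, adjusted p = 7.88e-13, and adjusted p = 0.0853 with an estimated correlation). Otc changed by 1.98 ± 0.15, and Tat was at 0.48. Fatty acid oxidation genes rose in 24 of 27 and fell in 0 (24 adjusted over the list alone, median 0.96, adjusted p = 2.17e-10, and adjusted p = 0.142 with an estimated correlation). Acot1 changed by 3.95 ± 0.45. Bile acid genes rose in 19 of 23 and fell in 1 (Acox2, 20 called adjusted over the list alone, median 0.78, adjusted p = 8.52e-08, and adjusted p = 0.0853 with an estimated correlation). Cyp8b1 changed by 2.59 ± 0.35 and Cyp7a1 (the rate-limiting enzyme of bile acid synthesis) by 1.95 ± 0.44. Glucose genes rose in 15 of 20 (16 called adjusted over the list alone, median 0.58, adjusted p = 0.000186, and adjusted p = 0.142 with an estimated correlation), while Igfbp1 fell (−1.30). Lipogenesis genes rose in 12 and fell in 3 of 25 (Scd2, Dgat1 and Lpl, 15 called adjusted over the list alone, median 0.46, adjusted p = 0.0287, and adjusted p = 0.397 with an estimated correlation).

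Extracellular matrix genes fell in 9 of 22 and rose in 0 (9 adjusted over the list alone, median −0.48, adjusted p = 0.0748), with Col1a2 at −1.07 ± 0.35 and Dcn at −0.73 ± 0.12. Stellate cell genes fell in 12 and rose in 1 of 21 (Tpm2, 13 called adjusted over the list alone, median −0.74, adjusted p = 0.002, and adjusted p = 0.306 with an estimated correlation). Timp1 changed by −3.37 ± 0.32. Remodelling genes fell in 11 and rose in 1 of 23 (Ctsl, 12 called adjusted over the list alone, median −0.44, −0.34 at the bound, adjusted p = 0.00209, and adjusted p = 0.306 with an estimated correlation). Mmp9 changed by −3.70 ± 0.25. Endothelial genes fell in 13 and rose in 3 of 25 (Oit3, Dnase1l3 and Tek, 16 called adjusted over the list alone, median −0.32, adjusted p = 0.0154, and adjusted p = 0.395 with an estimated correlation). Vcam1 changed by −1.49 ± 0.15. Cholangiocyte genes fell in 6 of 15 (6 adjusted over the list alone, median −0.19, 0 at the bound, adjusted p = 0.0287, and adjusted p = 0.306 with an estimated correlation). Not called by camera were the other 11 lists and the matrix list above. T cell genes fell in 5 of 18 and rose in 0 (Cd3d, Cd8b1, Ctla4, Cd27 and Thy1, median −0.25, −0.19 at the bound, adjusted p = 0.132). B cell genes fell in 5 and rose in 1 of 14 (Sdc1 rose, Mzb1 −2.05 ± 0.40, median −0.30, −0.27 at the bound, adjusted p = 0.136). Interferon-stimulated genes rose in 4 (Ifit3, Oasl1, Usp18 and Ifi27) and fell in 5 of 25 (Oas1g, Oas2, Oasl2, Cmpk2 and Gbp2, adjusted p = 0.965), with a median of 0.05 but a mean of −0.05. Cholesterol synthesis genes rose in 5 and fell in 3 of 18 (Sqle, 0.16 within BeadChip 2, Lss and Srebf2, adjusted p = 0.522), with a median of −0.01 but a mean of 0.11. Plasma protein genes rose in 21 and fell in 10 of 52 (median 0.08, adjusted p = 0.136). Oxidative stress genes rose in 9 and fell in 9 of 28 (adjusted p = 0.965), with a median of 0.13 (0.11 at the bound) but a mean of −0.15. Erythroid genes rose in 4 (Klf1, Fech, Hebp1 and Fth1) and fell in 9 of 14 (median −0.80, −0.78 at the bound, adjusted p = 0.136). Clock genes rose in 6 and fell in 3 of 18 (Per1, Nfil3 and Nampt fell, Dbp 3.34 ± 0.36, median 0.10, adjusted p = 0.147). Of 11 pancreas genes Ctrb1 and Spink1 (−4.69 ± 0.33) fell (median −0.68, −0.41 at the bound, adjusted p = 0.156). Of 8 fat and muscle genes Adipor2, Car3 and Actn3 rose (median 0.21, 0 at the bound, adjusted p = 0.0792). Reference genes fell in 7 and rose in 1 of 12 (B2m, median −0.29, adjusted p = 0.0627). Adjusted over the list alone, the calls in these 11 lists numbered 4, 6, 8, 7, 31, 19, 13, 9, 1, 3 and 8 in the order given.

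The residual comparison asks what still differed from uninfected livers after treatment, where both groups had praziquantel (9 against 9 arrays). The largest rise was in Gpnmb, a glycoprotein gene of macrophages (chromosome 6, 49036518 to 49058182): 8.94 ± 1.05 in treated and 4.93 ± 0.48 in uninfected livers (SD, n = 9 each, detected on 2 of 9 uninfected arrays), at least 14.4-fold higher. The macrophage elastase gene Mmp12 (chromosome 9, 7344397 to 7360461) was at least 5.17-fold (detected on 1 of 9 uninfected arrays), the ubiquitin-like Ubd at least 5.18-fold (on 3) and Prg2 at least 4.1-fold higher (on 1, and on 8 of 9 treated ones). Fxyd6 (on 8) rose by 2.31 ± 0.38, Loxl1 by 2.26 ± 0.38, the MHC class I gene H2-M2 by 2.20 ± 0.46 and the protease inhibitor gene Slpi by 2.17 ± 0.39. Falls with no overlap between the arrays within each week were smaller: Ugt1a2 (−1.34 ± 0.19), the sterol enzyme gene Nsdhl (−1.33 ± 0.21), Cth (−1.31 ± 0.21), Glud1 (glutamate dehydrogenase, −1.23 ± 0.20), Acad8 (−1.19 ± 0.16), Asl (−1.16 ± 0.27), Mtch2 (−1.12 ± 0.15) and Gramd3 (−1.08 ± 0.15). In all 3102 genes were called (1876 higher, 1226 lower), 160 of them at least 2-fold (134 higher, 26 lower), and 3251 with the BeadChip as a block. Within BeadChips 59 of 97 named genes had the same sign in each of 9 differences. In the mean of weeks 13 and 14 only, 784 genes were called, 772 of them among the 3102. Without the 2 arrays that stand apart, 2461 were called, 2368 of them among the 3102.

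Of 22 extracellular matrix genes 14 were higher in treated than in uninfected livers and 0 lower (16 adjusted over the list alone, median 0.60, adjusted p = 6.23e-05, and adjusted p = 0.699 with an estimated correlation). Col3a1 changed by 1.55 ± 0.34, Col6a1 by 1.40 ± 0.31 and Col1a2 by 1.35 ± 0.35. Remodelling genes were higher in 10 of 23 (16 adjusted over the list alone, median 0.37, adjusted p = 0.000674, and adjusted p = 0.699 with an estimated correlation). Mmp2 changed by 1.74 ± 0.37 and Ctsk by 1.62 ± 0.29. Stellate cell genes were higher in 10 of 21 (10 adjusted over the list alone, median 0.39, 0.29 at the bound, adjusted p = 0.00205, and adjusted p = 0.699 with an estimated correlation). Timp1 was at least 3.4-fold higher and Pdgfrb rose by 0.94 ± 0.17. T cell genes were higher in 8 of 18 (10 adjusted over the list alone, median 0.36, 0.16 at the bound, adjusted p = 0.00112, and adjusted p = 0.699 with an estimated correlation). Cd8b1 changed by 1.67 ± 0.21. MHC class II genes were higher in 7 of 13 (7 adjusted over the list alone, median 0.71, 0.62 at the bound, adjusted p = 0.00244, and adjusted p = 0.699 with an estimated correlation). H2-DMb1 changed by 1.65 ± 0.25. NK cell and type 1 genes were higher in 6 of 15 (6 adjusted over the list alone, median 0.25, 0.15 at the bound, adjusted p = 0.00942, and adjusted p = 0.699 with an estimated correlation). Ccl5 changed by 1.53 ± 0.27. Neutrophil genes were higher in 8 of 16 (10 adjusted over the list alone, median 0.91, 0.73 at the bound, adjusted p = 0.00384, and adjusted p = 0.699 with an estimated correlation). S100a9 changed by 2.81 ± 0.54. Within the treated week 13 group, replicate 3 lay above the other 2 arrays by a median of 1.19 in the neutrophil, 0.97 in the matrix, 0.76 in the MHC class II, 0.71 in the B cell and 0.61 in the stellate cell list. It also lay above them by 0.57 in the remodelling, 0.56 in the macrophage, 0.49 in the T cell and 0.20 in the NK cell list.

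Lower in treated livers were 5 of 23 bile acid genes, with 0 higher (5 adjusted over the list alone, median −0.15, adjusted p = 0.0101, and adjusted p = 0.699 with an estimated correlation). The transporter Slco1a4 changed by −1.08 ± 0.17. P450 genes were lower in 7 of 42 (7 adjusted over the list alone, median −0.12, −0.11 at the bound, 0.019 within BeadChip 1, adjusted p = 0.0206, and adjusted p = 0.699 with an estimated correlation). Cyp2b10 changed by −1.16 ± 0.22, while Cyp1a2 rose (0.51). Cholesterol synthesis genes were lower in 3 of 18 (3 adjusted over the list alone, median −0.25, adjusted p = 0.0206, and adjusted p = 0.699 with an estimated correlation), namely Nsdhl, Pmvk (−0.58) and Ebp (−0.30). Fry called neither the P450 (adjusted p = 0.207) nor the cholesterol list (adjusted p = 0.169). The other 21 lists were not called by camera. Among them macrophage genes were higher in 8 of 22 (10 called adjusted over the list alone, median 0.29, adjusted p = 0.0612), with Lgals3 at 1.49 ± 0.24 and Trem2 at 1.03 ± 0.30, while the Kupffer cell genes Vsig4 (−0.44) and Timd4 (−0.55) were lower. Eosinophil genes were higher in 2 of 6 (Prg2 and Rnase2a, adjusted p = 0.0961). Type 2 genes were higher in 5 and lower in 2 of 22 (adjusted p = 0.197, Chil3 at least 2.66-fold and Retnla at least 2.84-fold higher, Cd163 −1.05 ± 0.22). B and plasma cell genes were higher in 1 of 14 (Mzb1, 2.31 ± 0.40, adjusted p = 0.395), and endothelial genes in 8 of 25 (adjusted p = 0.0959, Vwf 1.29 ± 0.11). Acute phase genes were higher in 4 of 29 (1 adjusted over the list alone, median 0.05, adjusted p = 0.56): Lcn2 (1.34 ± 0.43, −0.12 within BeadChip 1), Saa3 (1.12 ± 0.21), Il1rn (0.68) and Crp (0.20). Cell cycle genes were higher in 3 and lower in 1 of 24 (Mcm4, Mcm6 and Mcm7 higher, Tyms lower, adjusted p = 0.56). Adjusted over the list alone, the calls in the eosinophil, type 2, B cell, endothelial and cell cycle lists numbered 2, 7, 1, 8 and 2.

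In the remaining 14 lists of the residual comparison adjusted p lay between 0.0605 and 0.745. Fatty acid oxidation genes were higher in 2 and lower in 3 of 27 (Decr2 −1.06 ± 0.18, Hadh −0.85 and Eci1 −0.68 lower), and urea cycle and amino acid genes higher in 1 (Glul, 0.59) and lower in 5 of 33, among them Cps1 and Nags (−0.71 ± 0.14). Lipogenesis genes were higher in 2 and lower in 3 of 25 (Lpl 1.68 ± 0.27 and Dgat1 higher, Gpam, Dgat2 and Lpin1 lower), glucose genes higher in 3 and lower in 2 of 20 (Gys2 and Foxo1 lower), and plasma protein genes higher in 7 and lower in 2 of 52 (Apoc2 and Serpind1). Of the interferon-stimulated genes 5 of 25 were higher (Oas1g, Oasl2, Bst2, Igtp and Gbp2) and 2 lower (Ifih1 and Ddx58). Mast cell genes were higher in 2 of 6 (Hdc and Gata2) and cholangiocyte genes in 3 of 15 (Igf2 1.24 ± 0.29, Anxa2 1.19 ± 0.16 and Gpc3 1.00, the last −0.027 within BeadChip 3). Oxidative stress genes were higher in 4 (Gpx3, Cyba, Ncf1 and Ncf4) and lower in 4 of 28 (Nqo1, Gsta2, Cat and Gpx1, median −0.02, mean 0.03). Single genes were called in the erythroid (Fech −0.75), clock (Bhlhe40 0.61) and pancreas lists (Spink1 at least 1.66-fold, −0.088 within BeadChip 3), 0 of 8 in the fat and muscle list and 2 of 12 reference genes (Actb, with its probes called in opposite directions, and Ywhaz). Adjusted over the list alone, the calls numbered 3, 6, 5, 5, 7, 7, 2, 3, 9, 1, 0, 0, 0 and 2 in the order given.

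**Figure D2:**
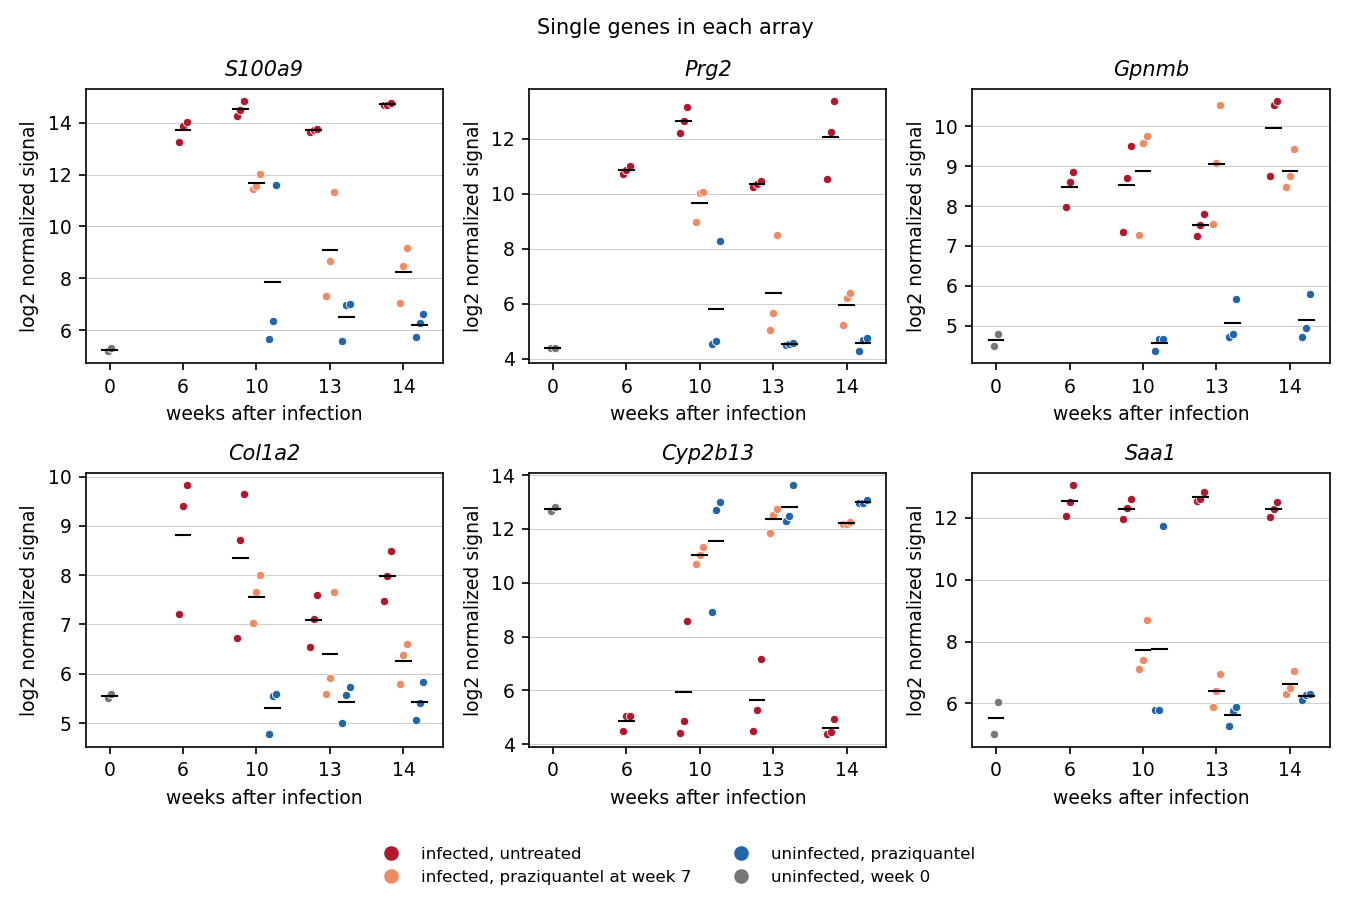
Log2 normalized signal of S100a9, Prg2, Gpnmb, Col1a2, Cyp2b13 and Saa1 by week, 1 point per array, by group. Gpnmb has week means of 8.87, 9.06 and 8.89 in treated livers and 4.58, 5.06 and 5.16 in uninfected ones, where 0, 1 and 1 of 3 arrays detected it.

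By week, infection changed 5526 genes at week 10, 3903 at week 13 and 5779 at week 14 (5660, 4064 and 5916 with the BeadChip as a block). S100a9 stood at 14.52 ± 0.28, 13.71 ± 0.06 and 14.71 ± 0.06 in untreated livers at weeks 10, 13 and 14, at 11.67 ± 0.32, 9.10 ± 2.04 and 8.23 ± 1.08 in treated and at 7.87 ± 3.24, 6.51 ± 0.80 and 6.21 ± 0.46 in uninfected ones (SD, n = 3). Treatment changed 2917, 2148 and 4902 genes (3112, 2259 and 5022 with the block). Leaving out untreated week 10 replicate 2 gave 1719 at week 10, and leaving out untreated week 13 replicate 1 gave 1417 at week 13. With only the arrays compared, 1491 were called at week 10 and 1424 at week 13.

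Between treated and uninfected livers, 2412 genes were called at week 10 (1392 higher, 1020 lower), 42 at week 13 and 7 at week 14 (2543, 21 and 5 with the block). With only the arrays compared, limma called 0 at week 13 (1409 unadjusted) and 38 at week 14. Without the 2 arrays that stand apart there were 2 at week 13, 1 of them among the 42, and 58 at week 14, and array weights gave 15 and 267. Gpnmb was higher at each week, at least 14.2-fold at week 10 and by 4.0 and 3.73 at weeks 13 and 14 (± 0.63 each, n = 3 against 3), and so was Vwf, by 1.27, 1.48 and 1.1. At week 14 the other called genes were Ctsa (a lysosomal protease, −1.20 ± 0.22), Eif3c (−0.90 ± 0.16), Kdelr2 (−1.20 ± 0.18), Mcu (the mitochondrial calcium uniporter, −1.31 ± 0.21) and 1 probe with no symbol. At unadjusted p under 0.05 the counts were 1844 at week 13 and 1438 at week 14. Without treated week 10 replicate 3, 1277 genes were called at week 10. The week 13 count was 304 without treated replicate 1, 1 without treated replicate 3, 8 without uninfected replicate 1 and 7 without uninfected replicate 3. The week 14 count by limma was 0 without treated replicate 2 (959 unadjusted), 4 without treated replicate 3, 0 without uninfected replicate 2 (1097 unadjusted) and 2 without uninfected replicate 3.

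The week 6 comparison sets infected livers before treatment against uninfected livers of week 0 (3 against 2 arrays, which share no array with the later weeks), so infection and time go together in it. Lcn2 rose by 8.79 ± 0.83, S100a9 by 8.47 ± 1.05, S100a8 by 8.07 ± 1.06, Slpi by 7.28 ± 0.75 and Saa3 by 7.25 ± 0.40, and Ltf was at least 183-fold, Mpo at least 141-fold and Prtn3 at least 104-fold higher. Among genes with 1 symbol, the largest falls were in Cyp2b13 (−7.89 ± 0.93), Sult2a8 (−6.52 ± 0.52), Car3 (−6.18 ± 0.68), Cyp2b23 (−6.16 ± 0.59), Cyp4a14 (−5.85 ± 1.37), Cyp4a31 (−5.74 ± 0.84) and Acot3 (−5.50 ± 0.88). Cyp2b10 was at least 31-fold lower. In all 5461 genes were called (2913 higher, 2548 lower), 2706 of them at least 2-fold (1602 higher, 1104 lower), and 5647 with the block. All 124 named genes had the same sign in both within-BeadChip differences. Of the 2913 genes higher at week 6, 2618 (89.9%) were also higher in the infection mean of weeks 10 to 14 (949 if independent), 2212 (75.9%) lower with treatment (724 if independent) and 1280 (43.9%) higher in treated than in uninfected livers (474 if independent).

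Camera called 25 lists at week 6 and fry 28. With the series matrix values 3 of the 25 were no longer called: B cell (adjusted p = 0.0828), cholesterol synthesis (adjusted p = 0.0828) and clock genes (adjusted p = 0.0533). Higher were macrophage genes (22 of 22, median 2.84, adjusted p = 1.28e-12, and adjusted p = 0.107 with an estimated correlation) and acute phase genes (24 of 29, 1 lower, Hamp2, median 1.75, adjusted p = 2.64e-09, and adjusted p = 0.107 with an estimated correlation). Cell cycle genes (19 of 24, median 2.60, 2.07 at the bound, adjusted p = 2.64e-09, and adjusted p = 0.108 with an estimated correlation) were higher. So were neutrophil genes (13 of 16, median 5.60, 4.93 at the bound, adjusted p = 1.63e-07, and adjusted p = 0.14 with an estimated correlation), endothelial genes (19 of 25, median 1.05, adjusted p = 2.96e-06, and adjusted p = 0.14 with an estimated correlation) and MHC class II genes (11 of 13, median 2.62, adjusted p = 6.83e-06, and adjusted p = 0.161 with an estimated correlation). Matrix genes were higher in 17 of 22 (median 1.82, 1.48 at the bound, adjusted p = 5.37e-05, and adjusted p = 0.267 with an estimated correlation) and stellate cell genes in 14 of 21 (adjusted p = 4.23e-05, and adjusted p = 0.161 with an estimated correlation). Remodelling genes were higher in 15 of 23 (adjusted p = 0.000195, and adjusted p = 0.186 with an estimated correlation) and type 2 genes in 14 of 22 (adjusted p = 9.18e-05, and adjusted p = 0.107 with an estimated correlation). Eosinophil genes were higher in 5 of 6 (adjusted p = 0.00819, and adjusted p = 0.193 with an estimated correlation) and mast cell genes in 5 of 6 (adjusted p = 0.00219, and adjusted p = 0.161 with an estimated correlation). T cell genes were higher in 11 of 18 (adjusted p = 0.000525, and adjusted p = 0.186 with an estimated correlation) and B cell genes in 7 of 14 (adjusted p = 0.0277, and adjusted p = 0.375 with an estimated correlation). NK cell genes were higher in 9 of 15 (adjusted p = 0.00328, and adjusted p = 0.198 with an estimated correlation) and interferon-stimulated genes in 11 of 25, with Ddx58 lower (adjusted p = 0.012, and adjusted p = 0.345 with an estimated correlation). Col1a2 rose by 3.26 ± 0.67, Timp1 was at least 69.2-fold and Chil3 at least 80.8-fold higher, and Gbp2 rose by 3.62 ± 0.42.

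Lower at week 6 were P450 genes (33 of 42, median −1.43, adjusted p = 3.02e-12, and adjusted p = 0.107 with an estimated correlation) and urea cycle and amino acid genes (28 of 33, median −1.67, adjusted p = 7.1e-12, and adjusted p = 0.107 with an estimated correlation). Fatty acid oxidation genes were lower in 21 of 27 (adjusted p = 4.11e-08, and adjusted p = 0.161 with an estimated correlation) and bile acid genes in 15 of 23, with Acox2 higher (adjusted p = 5.82e-07, and adjusted p = 0.107 with an estimated correlation). Glucose genes were lower in 15 of 20, with Igfbp1 higher (adjusted p = 2.07e-05, and adjusted p = 0.108 with an estimated correlation), and lipogenesis genes in 15 of 25, with Scd2, Dgat1 and Lpl higher (adjusted p = 0.000942, and adjusted p = 0.193 with an estimated correlation). Cholesterol synthesis (7 of 18, 1 higher, Srebf2, adjusted p = 0.0144, and adjusted p = 0.427 with an estimated correlation), clock (9 of 18, 1 higher, Nfil3, adjusted p = 0.017, and adjusted p = 0.161 with an estimated correlation) and fat and muscle genes (3 of 8, adjusted p = 0.0186, and adjusted p = 0.107 with an estimated correlation) were also lower. Cyp2c29 (−4.91 ± 0.44), Cyp8b1 (−5.25 ± 0.68), Cth (−3.78 ± 0.40) and Slc2a2 (−3.90 ± 0.41) fell. Not called were plasma proteins (11 higher, 15 lower of 52), cholangiocytes (5 higher, 3 lower of 15: Krt23, Prom1 and Cldn7), oxidative stress (9 higher, 10 lower of 28, median −0.33, mean 0.15), erythroid (7 higher, 2 lower of 14), pancreas (1 higher, Spink1, 1 lower of 11, Cela1, median −0.28, mean 0.04) and reference genes (5 higher, 2 lower of 12). Adjusted p of these 6 lists by camera lay between 0.0743 and 0.776. Adjusted over the list alone, the number of calls differed by at most 2 genes in each of the 31 lists.

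The week 6 score, in which the 1602 higher and the 1104 lower genes of week 6 measure the later arrays, asks how far these genes returned. The higher genes lay 1.53 above uninfected livers in untreated and 0.43 above in treated livers, and the treated minus untreated difference was −1.1 (n = 9 each, exact permutation p = 0.00025, two-sided, the smallest that the 8000 relabellings within weeks can give, Benjamini-Hochberg 0.00025). The lower genes gave −1.27, −0.32 and 0.95 with the same p. The treated minus uninfected difference was also set as a share of the untreated minus uninfected difference of the same week. For the higher genes this share was 39.5% at week 10, 28% at week 13 and 17.5% at week 14. For the lower genes it was 33.1%, 26.9% and 16.8%. The base moved as well: untreated livers lay 1.59, 1.23 and 1.76 above uninfected ones in the higher genes. Treated livers lay 0.63, 0.34 and 0.31 above them, and −0.42, −0.28 and −0.25 from them in the lower genes. The smaller share at week 14 than at week 13 thus came mostly from the larger base. Without treated week 13 replicate 3 the week 13 shares were 14.8% and 16.3%, below those of week 14, so a steady decline over the 3 weeks is not shown. Within single BeadChips every difference kept its sign (treated minus uninfected 0.12 to 0.87 for the higher and −0.68 to −0.091 for the lower genes).

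**Figure D3:**
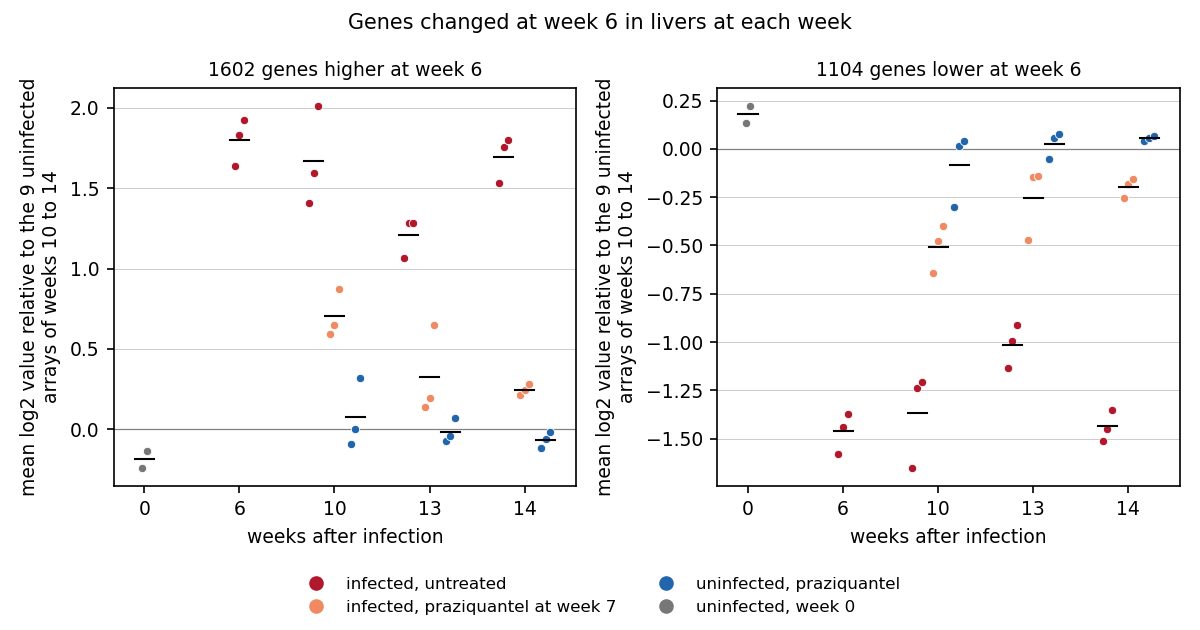
Week 6 score per array (log2, against the mean of the uninfected arrays of weeks 10, 13 and 14), for genes higher and genes lower at week 6, by group and week, with points for arrays and bars for means. The arrays of weeks 6 and 0 are also shown. The genes were chosen on them, so their separation is built in. The higher genes have means of 1.67, 1.21 and 1.70 in untreated and 0.71, 0.33 and 0.25 in treated livers at weeks 10, 13 and 14.

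The last comparisons ask what changed over time within a kind of liver (3 against 3 arrays each). In treated livers 200 genes differed between weeks 14 and 10 (69 higher, 131 lower). Lower at week 14 were Ltf (−4.30 ± 0.88), Prg2 (−3.73 ± 0.76), Retnlg (−3.52 ± 0.61, detected on 2 of 3 arrays), Camp (−3.41 ± 0.83) and Mpo (−3.27 ± 0.61, on 1 of 3). The peroxisomal oxidase gene Hao2 (2.39 ± 0.53), Cyp2b10 (1.57 ± 0.38), Kyat3 (1.21 ± 0.28), Gatad1 (1.19 ± 0.28) and Akr1c12 (1.02 ± 0.22) were higher. The count was 80 with the BeadChip as a block, 920 with array weights and 468 without the 2 arrays that stand apart. Leaving out week 10 replicates 1, 2 and 3 in turn gave 3, 101 and 1, and leaving out week 14 replicates 1, 2 and 3 gave 1, 49 and 21.

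In untreated infected livers 41 genes differed between weeks 14 and 10 (18 higher, 23 lower, 36 with the block). With only the arrays compared, limma called 0 of them (737 unadjusted), and array weights gave 535. The stefin genes Stfa1 (2.34 ± 0.39) and Cstdc4 (1.77 ± 0.39), Rhox5 (1.71 ± 0.33), Il1r2 (1.25 ± 0.26) and Ggt5 (at least 2.18-fold) were higher. The major urinary protein genes Mup6 (−2.28 ± 0.44) and Mup2 (−1.87 ± 0.31), Keg1 (−2.08 ± 0.35), Apol9b (−1.62 ± 0.26) and Oasl1 (−1.40 ± 0.26) were lower. The count was 3, 118 and 178 without week 10 replicates 1, 2 and 3, and 10, 154 and 7 without week 14 replicates 1, 2 and 3. Between weeks 10 and 6, 76 genes differed (39 higher, 37 lower, 82 with the block), by limma 0 with only the arrays compared (842 unadjusted) and 354 with array weights. Cyp8b1 (3.06 ± 0.61), Itgb2l (1.95 ± 0.27), Rdh16 (1.90 ± 0.26), Gpc3 (1.86 ± 0.41) and the neutrophil surface gene Cd177 (1.85 ± 0.40) were higher at week 10. Ccl24 (−2.02 ± 0.37), Saa3 (−1.83 ± 0.36), Cxcl2 (−1.67 ± 0.31), Marco (−1.57 ± 0.33) and Cdkn1a (−1.53 ± 0.34) were lower. That count was 17 and 31 without week 6 replicates 1 and 2, and 25, 138 and 127 without week 10 replicates 1, 2 and 3.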

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

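The test of the difference between the residual effects of weeks 14 and 10, the comparisons with the uninfected arrays of weeks 13 and 14 as control, those without the 2 arrays that stand apart and the BeadChip test of the week 10 residual count were chosen only after the result was seen.

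The effect of treatment differed between weeks 14 and 10 in 21 genes (5 higher, 16 lower), by a test of the difference itself. Retnlg (−4.52 ± 0.86) had a more negative effect at week 14, and so had Pglyrp1 (by at least 5.73-fold), Elane (5.47-fold), Pi16 (4.86-fold) and Cd177 (4.36-fold), which were detected on no treated week 14 array. Keg1 (2.39 ± 0.50), Rdh16 (1.76 ± 0.37), the Kupffer cell gene Timd4 (1.67 ± 0.30), Etfrf1 (1.08 ± 0.23) and Tor1a (1.05 ± 0.21) had a more positive one. The count was 5 with the BeadChip as a block, 578 with array weights and 89 without the 2 arrays that stand apart. It was 2 and 276 without untreated week 10 replicates 1 and 2, 1 and 2 without treated week 10 replicates 1 and 3, 1, 171 and 3 without untreated week 14 replicates 1, 2 and 3, and 2, 1 and 3 without treated week 14 replicates 1, 2 and 3. Among 100 splits drawn, 10 gave as many genes (the highest other 5474), so chance is not excluded. The splits that exchange the labels of 1 week turn the effect of treatment itself into a difference, which is a structure of the samples.

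The residual effect differed between weeks 14 and 10 in 16 genes (1 higher, 15 lower): Acbd5 (−2.52 ± 0.39), Bach1 (−2.09 ± 0.29), Nfic (−2.01 ± 0.25) and Ddx6 (−1.88 ± 0.18) had a more negative effect at week 14, and so had Dctn1, by at least 2.75-fold, which was detected on no uninfected week 10 array. Acbd5, Bach1, Ddx6 and Dctn1 were themselves higher in uninfected livers at week 14 than at week 10 (values under Other observations). For these genes a large part of the difference thus came from the uninfected arrays, not the treated ones. For Ddx6 the 3 uninfected week 10 arrays lay at 8.28 ± 0.18 (SD). Probes of Ddx6 (at week 6) and of Nfic (for infection, treatment and week 6) were called in opposite directions. For the difference between residual effects, other probes were not compared. The count was 15 with the BeadChip as a block, 34 with only the arrays compared, 78 with array weights and 31 without the 2 arrays that stand apart. It was 9 and 5 without treated week 10 replicates 2 and 3, 8 without uninfected week 10 replicate 3, 7, 10 and 10 without treated week 14 replicates 1, 2 and 3, and 7, 10 and 6 without uninfected week 14 replicates 1, 2 and 3. Of 100 splits, 10 gave as many genes (the highest other 2429), so chance is not excluded, with the same structure.

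For the means over weeks, 1 of 100 splits drawn, the real one, gave as many genes: 7156 for infection (highest other 6079), 5761 for treatment (3855) and 3102 for the residual comparison (2391). This argues against chance for these 3 counts, though 1 of 100 is the smallest share that the splits drawn can give. For the number of lists called by camera the splits cannot decide, and chance is not excluded. With 3 arrays of each kind in a week no split is balanced, so each keeps a part of the real difference. As many as the 21 lists of the infection mean came from 23 of 100 splits (highest other 26). For the 19 lists of the treatment mean it was 31 (25), and for the 10 of the residual mean 27 (20). Within single weeks the 10 splits are too few for a share under 0.05. The real and the highest other counts were 5526 and 68, 3903 and 0, and 5779 and 1 for infection at weeks 10, 13 and 14. They were 2917 and 1, 2148 and 1, and 4902 and 0 for treatment, and 2412 and 22, 42 and 3, and 7 and 0 for the residual comparison. Between weeks 14 and 10 they were 200 and 0 in treated and 103 and 1 in uninfected livers, again of 10 splits. In untreated livers 2 of 10 splits gave as many as the 41 genes between weeks 14 and 10 (highest other 602, in the split that sets week 10 replicates 1 and 3 and week 14 replicate 2 against the rest, which in part follows the BeadChips and separates these arrays on the first principal component, −56.4 to −48.5 against −80 to −68.1, and 36 genes with the BeadChip as a block). For weeks 10 and 6, 2 of 10 gave as many as 76 (highest other 124, 82 with the block). A split with several times the real count points to a structure of the samples.

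Acute phase and neutrophil genes were high in uninfected week 10 replicate 1: Saa1 stood at 11.7 there and at 5.78 in the mean of the other 2 arrays, Lcn2 at 13.6 and 8.44, and 11 of 29 acute phase genes lay over 1 log2 above the others. An infected liver under a wrong label is argued against: over 22 matrix and eosinophil genes called at week 10, the array reached a median share of −0.204 of the infection change (quartiles −0.331 and −0.0354), against 0.872 over the 14 acute phase genes called, although Prg2 was raised (8.27). The 22 genes were called with this array among the uninfected ones, which favours a low share. Over the whole matrix and eosinophil lists, fixed beforehand, the array lay a median of −0.40 and 0.02 from the other 2. The infected week 10 arrays lay 1.32 and 3.23 from the same 2 arrays. The BeadChip of replicate 1 is also argued against as the source. The uninfected week 13 array of the same BeadChip had a median acute phase shift of −0.0509, against 0.757 in replicate 1. No biological explanation was tested, as the labels name no difference for this mouse. Infection of this mouse at another stage, another illness or handling therefore stays open, untested.

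Between treated and uninfected livers 2412 genes were called at week 10, and 42 and 7 at weeks 13 and 14. An unusual uninfected week 10 group as the whole cause is argued against, since 78.6% of these genes (1896) were called the same way against the uninfected arrays of weeks 13 and 14. Treated and uninfected week 10 arrays both lie on BeadChips 1, 2 and 4, 1 array each, so a constant difference between BeadChips cancels. With the BeadChip as a block 97.9% (2361) were called the same way. This share decides nothing, since the balance leaves the log2 changes as they are. A candidate explanation is a change that was left after treatment and was smaller but still present later: 95.5% (2304) had the same direction in weeks 13 and 14, against 73.8% of all genes, with a median size of 0.301 there and 0.709 at week 10. The size at week 10 is raised by the choice of genes called at that week. The test of the difference between weeks 14 and 10 called only 16 genes, and without treated week 10 replicate 3 the week 10 count was 1277, so how much the effect shrank stays open.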

How the results depend on the processing

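The alternatives without the 2 arrays that stand apart, with the uninfected arrays of weeks 13 and 14 as control and with the mean of weeks 13 and 14 only, and the residual difference between weeks, were chosen only after the result was seen. Counts for infection (the mean, each week and week 6), the treatment mean, treatment at week 14 and the residual effect at week 10 stayed within 1.5 times the reported value under every alternative other than leaving out arrays, and so did the means under the latter. No named gene changed direction under another scaling, background or filter. Of 534 values of named genes, 493 (only the arrays compared) to 534 (BeadChip as a random block) kept direction and call under each alternative run on all arrays or on those compared, and 7034 of 7360 when single arrays were left out. Of 345, 291 did so in the mean of weeks 13 and 14. Within BeadChips 1 to 4, 169 of 489, 236 of 519, 134 of 365 and 113 of 365 values moved by more than the spread between replicates, and 11 values reversed, and the cause was not tested: for infection Tef (0.10) and Cela1 (0.036) in BeadChip 4, for treatment Sqle (0.16) in BeadChip 2, and for the residual comparison Cygb (−0.18), Ms4a7 (−0.28), Gbp2 (−0.12), Gpc3 (−0.027), Vcam1 (−0.14) and Spink1 (−0.088) in BeadChip 3 and Tkfc (−0.11) and Lcn2 (−0.12) in BeadChip 1. The residual P450 list had a median of 0.019 in BeadChip 1, fry no longer called this list or the residual cholesterol list, the series matrix no longer called 3 lists at week 6 (B cell, cholesterol and clock), and fry turned the direction of the oxidative stress list for infection (median −0.12). Median scaling moved the median of all genes by −0.142 for infection and 0.132 for treatment at week 10, −0.147 between weeks 10 and 6, 0.107 between uninfected weeks 10 to 14 and week 0 and −0.120 in the treatment difference, and the series matrix moved it by −0.133 at week 6. With an estimated correlation camera called 0 lists in each of the 4 comparisons (5, 10, 0 and 11 unadjusted for infection, treatment, residual and week 6, and 28, 26, 13 and 28 by fry), since the correlation it estimates within lists widens the test. Some lists not called by camera were called under an alternative. With the BeadChip as a fixed block this was 1 list for treatment. The series matrix added 2 lists for infection, 1 for treatment and 2 for the residual comparison. Fry added 6 for infection, 7 for treatment, 5 for the residual comparison and 3 at week 6. It also called the oxidative stress list for infection, in the turned direction named above. Leaving out the 2 arrays that stand apart added 1 for treatment and 3 for the residual comparison. Genes near the background, whose signal limits what arrays can show, carry the bounds given with them.

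The following counts moved by over 1.5 times, and the cause was not tested. The mean of weeks 13 and 14 only gave 784 residual genes. With only the arrays compared, limma called 1491 (treatment, week 10), 1424 (treatment, week 13), 0 (residual, week 13, 1409 unadjusted), 38 (residual, week 14), 0 (untreated, weeks 14 and 10, 737 unadjusted), 0 (weeks 10 and 6, 842 unadjusted), 3 (uninfected, weeks 14 and 10), 74 (uninfected against week 0) and 34 (residual difference). No background correction gave 145 and 23 (residual, weeks 13 and 14), 345 (treated, weeks 14 and 10), 87 (untreated), 159 (weeks 10 and 6) and 78 (treatment difference). Median scaling gave 17 (residual, week 13), 241 (weeks 10 and 6), 470 (uninfected against week 0), 105 (treatment difference) and 10 (residual difference). The series matrix gave 157 and 28 (residual, weeks 13 and 14), 409 (treated), 181 (weeks 10 and 6) and 65 (treatment difference). All probes gave 112 and 90 (residual, weeks 13 and 14), 68 (untreated) and 158 (uninfected), and the stricter filter 345 (treated) and 34 (treatment difference). The BeadChip as a fixed block gave 21 (residual, week 13), 80 (treated) and 5 (treatment difference), as a random block 36 (treatment difference), and the replicate block 15 (residual, week 13). Array weights gave 15 and 267 (residual, weeks 13 and 14), 920 (treated), 535 (untreated), 354 (weeks 10 and 6), 312 (uninfected), 85 (uninfected against week 0), 578 (treatment difference) and 78 (residual difference). The prior with trend and robust gave 64 (untreated) and 32 (treatment difference). Without the 2 arrays that stand apart there were 2 and 58 (residual, weeks 13 and 14), 468 (treated), 27 (uninfected), 89 (treatment difference) and 31 (residual difference).

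Leaving out each array in turn gave 6967 to 7249 genes for the infection mean, 5423 to 5933 for treatment and 2404 to 3190 for the residual mean. By week the ranges were 4607 to 5623, 3074 to 3592 and 5141 to 5594 for infection, 1719 to 3310, 1417 to 2389 and 4097 to 4788 for treatment, and 1277 to 2055, 1 to 304 and 0 to 6 for the residual comparison. Week 6 gave 4375 to 5254, treated livers over time 1 to 101, untreated 3 to 178, weeks 10 and 6 17 to 138, uninfected 23 to 66 and against week 0 71 to 257. The treatment difference gave 1 to 276 and the residual difference 5 to 16. Each array behind a move of over 1.5 times is named beside its count in the other parts.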

Other observations

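The tests of hepatocyte and sex-biased genes and the count without the 2 arrays that stand apart were chosen only after the result was seen.

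Uninfected livers, all given praziquantel, differed between weeks 14 and 10 in 103 genes (68 higher, 35 lower, 3 against 3 arrays, 122 with the BeadChip as a block). With only the arrays compared, 3 genes were called, and with array weights 312. Acbd5 (1.70 ± 0.28), the haem-binding repressor gene Bach1 (1.68 ± 0.21), the succinate receptor gene Sucnr1 (1.64 ± 0.39) and Ddx6 (1.56 ± 0.13) were higher at week 14 and Dctn1 at least 2.44-fold higher, while the cell cycle genes Cdc20 (−1.76 ± 0.41) and Cdkn1a (−1.48 ± 0.34), C6 (−1.38 ± 0.30), Nfil3 (−1.37 ± 0.29) and Emilin2 (−1.29 ± 0.30) were lower. Without the 2 arrays that stand apart, 27 genes were called. The count was 25, 49 and 66 without week 10 replicates 1, 2 and 3, and 23, 23 and 33 without week 14 replicates 1, 2 and 3.

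Uninfected livers of weeks 10 to 14 (9 arrays, praziquantel) differed from the untreated week 0 livers (2 arrays) in 256 genes (147 higher, 109 lower, 225 with the block, 74 with only the arrays compared, 85 with array weights), a comparison in which time and drug go together. The neurotrophin receptor gene Ntrk2 (2.10 ± 0.30), the lamin gene Lmnb1 (1.82 ± 0.24), Dct (1.73 ± 0.42), Hebp1 (1.56 ± 0.21) and Acpp (1.49 ± 0.39) were higher, and the mitochondrial carrier gene Slc25a25 (−2.01 ± 0.54), Tnfrsf12a (−1.34 ± 0.33), Dynll2 (−1.27 ± 0.29) and Hykk (−1.23 ± 0.23) were lower, with Adam20 at least 1.5-fold lower. Without week 0 replicate 2 the count was 71.

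Of 197 genes in the hepatocyte lists, 163 were called in the infection mean, 139 lower and 24 higher. A lower share of hepatocytes in the tissue as the whole cause is argued against, since it would lower these genes alike: the interquartile range of the genes called lower was 1.12, against a median SE of 0.143. Whether a loss of female-biased expression in these female livers adds to the falls stays open. The genes were listed as sex-biased from general knowledge, with no source file, after some of them had been seen. Over those in no fixed list and not seen before, the medians of 7 female-biased and 10 male-biased genes differed by −1.35, but 4 of the 10 (Susd4, Cspg5, Ihh and Dsg1c) were detected on at most 4 of 9 uninfected arrays and had little room to fall, so this difference decides nothing. Over the 6 and 6 genes detected on all 9 uninfected arrays the difference was −0.858 (exact permutation p = 0.0671, two-sided, 924 relabellings, across genes, which are not independent replicates). A smaller share of hepatocytes as a part of the falls also stays open.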
